A study of Mus musculus with 5 samples.

How the data were processed

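RNA-seq libraries of NIH3T3 cells that stably express a dCas9 activator were compared 48 h after transfection with sgRNA plasmids, 2 with scramble sgRNA and 3 with sgRNA against LINE-1. Groups and replicate numbers come from the sample titles. The labels name RNeasy total RNA and the NEBNext Ultra II RNA library kit. They do not say whether replicates were separate cultures or transfections, so the p-values measure only the spread between these libraries. One guide set was used per group, and guide sequences are not given in the sources used here.

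The deposited workbook holds 3 tables with a value for each library: 21259 cellular genes by symbol, 50 endogenous retrovirus (ERV) loci from ERVMap, and 18538 repeat names from RepEnrich, 17171 of them simple repeats. Its values are a normalized signal made by the authors, called normalized counts in the workbook's name. The submitters' processing notes name STAR 2.5.3a, Bowtie2 2.2.9, bedtools 2.27.1, SAMtools 1.9 and DESeq2, with the builds mm10 and GRCm38, but not the role of each tool. Counting settings, strandedness, the treatment of reads that fit several places and repeat positions are not given in the sources used here. In each library 100% of the values are whole multiples of the smallest value above 0, within 0.0001 reads, so in the gene and repeat tables dividing by that value gave whole reads. The ERV table has the same step per read as the gene table, so its reads were recovered with that step, and the repeat table has its own. Recovered reads per library were 30681384 and 36726985 for scramble and 40791356, 45596490 and 35996907 for LINE-1 sgRNA in the gene table, and 869941, 965497, 1093643, 1146936 and 967154 in the repeat table. The 10 most abundant genes held 3.88 to 4.50% of a library and the 10 most abundant repeat names 34.3 to 37.7%. Between libraries of a group, recovered gene reads varied with a chi-square of 3.01 to 8.66 per degree of freedom and repeat reads with 2.29 to 6.30, where counting error alone gives about 1.

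Gene symbols were searched for names turned into dates, and the ERV loci for repeated rows. The gene and repeat tables were not searched for repeated rows, and some genes, such as Ifnl2 and Ifnl3, have identical values. Among the genes, 24 symbols had been turned into dates and hold 0.219% of the signal; they were kept under those names. The loci Pmv19 and Pmv6 have identical values. Gene positions were taken from GENCODE release M 21 (GRCm38) for 21152 symbols with 1 position; 107 had none or several. Of these genes 3824 overlap another gene of the table, and reads in such overlaps cannot be assigned to a gene without knowing the strand. Among the list members named below this holds for Irf3, Ppp1r15a, Hspd1, Adar, Trex1, Setdb1, Tk1, Cyp51 and Hist1h2be. It also holds for Tdrd9, Tex14, Cd52, Ovol1, Esrp2, Egfl7 and Plin4.

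Each table was fitted on its own in R 4.3.3 with limma 3.58.1 on log2 of the value plus 1, without a further scaling, with a variance trend except for the ERV loci. Features with a mean of at least 10 over the 5 libraries were tested: 14337 genes, 1257 repeat names and 16 ERV loci. A feature passed at a Benjamini-Hochberg adjusted p below 0.05 within its table. Sums of normalized reads over repeat groups were compared by a two-sided exact permutation test, for which 2 against 3 libraries allow no p below 0.1. Fold changes of means are given as measured; where all scramble libraries were at 0, the bound uses a floor of 3 reads per scramble library and covers counting error only.

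The named cellular genes are, among genes past the threshold with a mean of at least 50 and every LINE-1 sgRNA library on the same side of both scramble libraries, the 12 largest rises and 12 largest falls, and up to 4 members of each gene list with the smallest p. Named repeats are every tested L1Md subfamily and the 10 largest rises and falls past the threshold. Genes and repeats named outside this rule were chosen after their values were seen. The 23 gene lists cover interferon-stimulated genes, nucleic acid sensing, NF-kB and inflammatory genes, p53 targets, unfolded protein and integrated stress response, cytosolic heat shock, LINE-1 silencing and restriction factors, mitotic and S-phase genes, fibroblast matrix, myofibroblast with SRF and YAP targets, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded transcripts, replication-dependent histones, ribosomal proteins, 2-cell-like and germline genes, and markers of leukocytes, epithelium, endothelium, adipocytes, muscle and neural cells. The 22 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists. The repeat table has no class column, so the 13 repeat groups were formed from the start of each name; only the rules for the 3 LINE-1 groups were fixed beforehand.

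Alternatives were pseudocounts of 0.5 and 8, no filter on low values or a mean of at least 50, TMM factors from edgeR 4.0.16, scaling to the table total, limma without the variance trend (with it for ERV loci), the replicate number as a block, each library left out in turn, and edgeR's quasi-likelihood test and DESeq2 1.42.0 on recovered reads (for the ERV loci with the deposited size factors and, in DESeq2, a mean dispersion). For lists and groups, camera with an estimated correlation and fry were run. When 1 of the 2 scramble libraries was left out, the remaining one was taken to vary like the LINE-1 sgRNA libraries.

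The procedure was tested on simulated data with 2 against 3 libraries of this depth and spread. In simulated gene tables limma found 73.1% of changes of 1.5-fold, 85.1% of 2-fold and 97.0% of 4-fold, and 6.59% of its 182 calls were unchanged genes. In simulated repeat tables the shares were 62.7%, 79.1% and 97.0%, with 8.09% of calls unchanged. Camera called 0 of 22 lists with no planted change and found the list that was raised 1.5-fold. Genes were simulated independently, so this does not test camera on correlated genes. In the data the estimated correlation reached 0.608, in ribosomal proteins. Few changes were planted and the scaling was known, so errors from the scaling between libraries were not tested either. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.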

Results

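The series asked how the transcriptome responds when LINE-1 retrotransposons are switched on by CRISPR activation. The cells were NIH3T3, an established mouse embryonic fibroblast line, carrying a dCas9 activator, a Cas9 protein that binds DNA without breaking it and raises transcription where a single guide RNA (sgRNA) places it. RNA was sequenced 48 h after transfection of sgRNA plasmids, with 2 libraries for scramble sgRNA and 3 for LINE-1 sgRNA. The values divide back into 30681384 to 45596490 reads per library for cellular genes and 869941 to 1146936 reads per library for repeats. Levels below are mean normalized read counts ± SD, with n = 2 scramble libraries and n = 3 LINE-1 sgRNA libraries throughout, and changes are LINE-1 sgRNA over scramble on the log2 scale with adjusted p from limma.

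The L1Md subfamilies, the mouse LINE-1 names that include the young elements, rose only in part. Among the L1Md subfamilies, L1MdTf_I rose by 1.06 (SE 0.099, adjusted p = 5.4e-07), from 321 ± 11.3 to 672 ± 39.6 normalized reads. L1MdA_I rose by 1.03, from 333 ± 8.61 to 684 ± 39.6, and L1MdGf_I by 1.01, from 339 ± 5.98 to 685 ± 39.9. L1MdN_I, L1MdF_II, L1MdF_I and L1MdA_II rose by 0.98, 0.98, 0.93 and 0.86, and L1MdTf_II rose by 0.71, from 508 ± 0.217 to 832 ± 55.0. These 8 of 25 L1Md subfamilies passed, all were higher in every LINE-1 sgRNA library than in both scramble libraries, and none of the 25 passed as lower. Adjusted over the list alone, 9 subfamilies passed, the added one being L1MdF_III (0.26, from 1326 ± 28.1 to 1591 ± 26.5, adjusted p = 0.060 over all repeats and 0.024 over the list). Over all repeats it passed with a mean of at least 50 (0.043), after TMM rescaling (0.031), with table totals (0.0085) and without LINE-1 sgRNA library 2 (0.014). The other 16, which include the most abundant ones, had changes between -0.19 for L1MdFanc_II and 0.07 for L1MdA_VI, and none of these passed.

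The 8 subfamilies that passed were scarce, and their rises were almost equal in size, between 320.1 and 355 normalized reads each. Their recovered reads moved together from library to library with a chi-square of 0.0395 per degree of freedom, where independent counts would give about 1, so the 8 rises are not 8 separate measurements. The sum of all 25 L1Md subfamilies was 313282 ± 11753 in scramble and 289434 ± 23275 in LINE-1 sgRNA libraries. With this change of -7.61% the libraries of the groups overlapped (two-sided exact permutation p = 0.5, where 2 against 3 libraries allow no p below 0.1). The 8 that passed together went from 2990 ± 63.7 to 5726 ± 346, a gain too small to show in that sum. The whole repeat table changed by -5.62% over the same libraries. LINE-1 sgRNA library 2 was the lowest in both sums, and weighs heavily in both changes. Its L1Md sum was 262724, against 300213 and 305366 in LINE-1 sgRNA libraries 1 and 3.

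**Figure D1:**
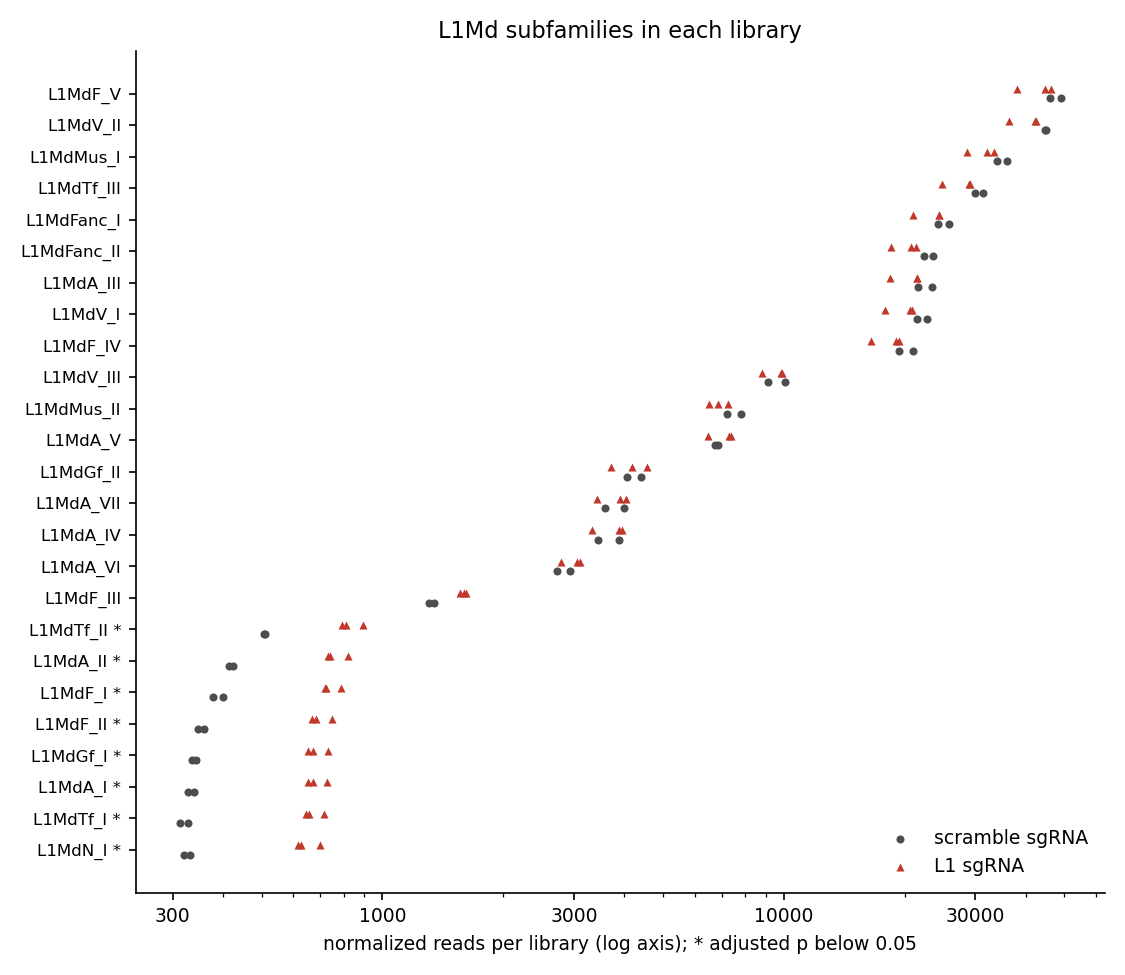
Normalized read counts (log axis) of the L1Md subfamilies in each library, with dots for scramble and triangles for LINE-1 sgRNA libraries and an asterisk at names that passed. The 8 subfamilies that rose lie at the low end, and L1MdTf_I went from 321 to 672 normalized reads.

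Older and rodent-specific LINE-1 subfamilies rose as well. Of 64 older LINE-1 subfamilies, 31 passed as higher and 1 as lower, with a median change of 0.56 (camera adjusted p = 6.6e-13; adjusted p = 0.537 with an estimated correlation). L1ME3 rose by 1.42 (from 19.6 ± 2.02 to 54.1 ± 3.83), L1MEj by 1.35 (from 39.4 ± 0.844 to 102 ± 6.73), L1ME5 by 1.30 and L1M4b by 1.28 (from 102 ± 4.12 to 250.3 ± 20.5). Of 27 rodent LINE-1 subfamilies, 14 passed as higher and none as lower, with a median of 0.30 (camera adjusted p = 2.9e-06; adjusted p = 0.319 with an estimated correlation). L1_Mus3, singled out after its values were seen, rose by 1.21, from 182 ± 1.46 to 423 ± 22.1. The L1Md group passed as raised (camera adjusted p = 0.0067; adjusted p = 0.568 with an estimated correlation; 0.072 without scramble library 2, where leaving out a library gave 8.9e-04 to 0.072). Its mean change was 0.26 while its median was -0.002, and the median was above 0 after TMM rescaling, with table totals and in edgeR. Whether older or rodent LINE-1 names share reads was not tested. The estimated correlation was 0.338 in the older and 0.0326 in the rodent group, against 0.177 in L1Md. The 31 older names therefore need not be 31 separate measurements. As with L1Md, the rises were in scarce names. The summed signal of the rodent group changed by -4.79% and that of the older group by -2.90%, with overlapping libraries in both (two-sided exact permutation p = 0.6 and 0.4). LINE-1 sgRNA library 2 was again the lowest in both.

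Endogenous retroviruses of the ERVB4_3 family fell. The internal part ERVB4_3-I_MM fell by 1.17 (SE 0.10, adjusted p = 4.7e-07), from 4607 ± 284 to 2060 ± 246 normalized reads. Its long terminal repeat ERVB4_3-LTR_MM fell by 1.22, from 556 ± 72.3 to 239 ± 37.2. The summed ERVB signal changed by -42.5%, from 6526 ± 275 to 3751 ± 331 (two-sided exact permutation p = 0.1, the lowest possible). ERVB4_3-I_MM made up most of that sum in scramble, so the sum is not separate evidence for the family. As a group of 17 subfamilies, with 1 higher and 2 lower, ERVB did not pass (camera adjusted p = 0.369). The terminal repeats RLTR6C_Mm (-0.71, from 1194 ± 8.58 to 728 ± 14.7) and RLTR6_Mm (-0.68, from 1724 ± 18.5 to 1078 ± 64.8) also fell. So did MER2 (-0.77), LTR37-int (-0.79), RMER16A2 (-0.73), the DNA transposon Tigger10 (-0.68) and the simple repeats _CCCATT_n (-1.38) and _AAATAA_n (-0.90). The largest rises outside LINE-1 were in the simple repeats _AACCA_n (2.82, from 7.93 ± 0.792 to 61.8 ± 2.92), _AGCCAATGC_n (1.95) and _CGCCCCT_n (1.80), then in MERV1_LTR (1.38) and the major satellite GSAT_MM (1.28, from 107 ± 14.8 to 276 ± 105). L1M7, an older LINE-1 name, rose by 1.38. Several of these calls depended on 1 library or on the settings. Without scramble library 1, _CCCATT_n (-1.07, adjusted p = 0.238), _AAATAA_n (-1.01, 0.135), LTR37-int (-0.77, 0.196), Tigger10 (-0.64, 0.067) and GSAT_MM (1.14, 0.074) no longer passed. Without scramble library 2, _CCCATT_n (-1.69, 0.053), _AAATAA_n (-0.80, 0.277), LTR37-int (-0.80, 0.192), RMER16A2 (-0.57, 0.254), Tigger10 (-0.71, 0.063), MERV1_LTR (1.01, 0.069) and L1M7 (1.29, 0.094) did not. _AAATAA_n also did not pass without LINE-1 sgRNA library 1 (-0.84, 0.071), with table totals (-0.82, 0.074), with no filter (0.063), without the variance trend (0.062) or in DESeq2 (-0.91, 0.296). The same held for LTR37-int with no filter (0.061), without the trend (0.151) and in DESeq2 (0.091), and for RMER16A2 with table totals (-0.65, 0.063) and in DESeq2 (-0.77, 0.224). GSAT_MM did not pass without the trend (0.099), nor did Tigger10 (0.082) and MERV1_LTR (0.054) in DESeq2.

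Across the repeat table, 156 of 1257 tested names passed, 118 higher and 38 lower (75.6% higher, and 87.0% of 162 calls when libraries were scaled to their table totals). The count was 62 without scramble library 2, with 59 of the 156 kept, 102 without scramble library 1, with 100 kept, and 77 without the variance trend, with 72 kept. In DESeq2 104 passed. The groups did not overlap for 40.6% of the names, where chance gives 20%. Of 13 groups of names, 4 passed in limma's camera: the 3 LINE-1 groups, and DNA transposons as lower (median -0.11, 0 higher and 2 lower of 37, adjusted p = 0.047; adjusted p = 0.537 with an estimated correlation). The last call was lost without scramble library 2 (adjusted p = 0.205), LINE-1 sgRNA library 1 (0.118) or LINE-1 sgRNA library 3 (0.061), where the lowest on leaving out a library was 0.014. The other groups did not pass in the same test: IAP had 2 higher and 3 lower of 23, rodent SINEs 3 and 0 of 28, MaLR and MT 12 and 0 of 77, RLTR 15 and 6 of 131, RMER 7 and 1 of 51, simple repeats 10 and 13 of 603, tRNA 3 and 0 of 6, and MIR, L2 and L3 no calls among 14. These splits varied with the scaling and tool. Simple repeats had 14 higher and 9 lower after TMM rescaling, 19 and 5 with table totals, 9 and 10 in edgeR and 4 and 7 in DESeq2. With table totals IAP had 2 and 1, rodent SINEs 7 and 0, and RMER 9 and 0. In DESeq2 IAP had 0 and 2, RLTR 7 and 6, MaLR and MT 8 and 0, tRNA 1 and 0, DNA transposons no calls, and older LINE-1 21 and 0. For 3 of the groups that did not pass, the outcome of camera depended on a library or the scaling. Simple repeats (adjusted p = 0.060) passed as lower after TMM rescaling (0.038) and without scramble library 1 (0.030), LINE-1 sgRNA library 1 (0.048) or LINE-1 sgRNA library 3 (0.0015), where the highest on leaving out a library was 0.446. The tRNA group (0.106) passed as raised without LINE-1 sgRNA library 3 (0.012, the highest on leaving out a library being 0.245). MIR, L2 and L3 (0.078) passed as lower without scramble library 1 (0.049) or LINE-1 sgRNA library 2 (0.036, the highest being 0.205). Median, mean and test differed in sign for ERVB (0.02, -0.06 and down), RLTR (0.007, 0.05 and down) and simple repeats (-0.04, 0.03 and down, with a median above 0 after TMM rescaling and with table totals), while the IAP median of -0.02 turned positive after TMM rescaling, with table totals and in edgeR.

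Cellular genes changed far more strongly than any repeat. Csrp3, which encodes a muscle LIM protein, had no read in either scramble library and reached 2669 ± 186 normalized reads with LINE-1 sgRNA, at least 899-fold higher against a floor of 3 reads per scramble library (adjusted p = 2.4e-18; GRCm38 chromosome 7, 48830398 to 48848033). Mcpt8, a mast cell and basophil protease gene, went from 2.43 ± 0.414 to 3791 ± 95.6 (log2 10.11, SE 0.13, adjusted p = 6.2e-19; chromosome 14, 56082166 to 56085273). The tight junction gene Cldn10 rose from 11.1 ± 4.06 to 12305 ± 368 (log2 10.04, SE 0.14, adjusted p = 1.2e-18; chromosome 14, 118787908 to 118875489). Kynu, a gene of tryptophan breakdown, went from 1.53 ± 0.871 to 1013 ± 52.6 (chromosome 2, 43555329 to 43682715), and the postsynaptic scaffold gene Shank1 from 13.6 ± 2.60 to 5218 ± 228 (log2 8.49; chromosome 7, 44310253 to 44360572). Shank1 overlaps 1700008O03Rik, which rose from 24.7 to 64.2, so the smaller of these rises cannot be assigned to one gene.

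Endou (log2 8.55), Adam3 (8.43), Trpv3 (8.09) and the orexin receptor gene Hcrtr1 (8.01, from 9.66 ± 3.06 to 2696 ± 22.1) were also among the largest rises, as were the neighbouring paralogs Spata31d1b and Spata31d1a on chromosome 13, whose scramble means of 0.535 became 1065 ± 20.3 and 597 ± 18.8. For such paralogs the assignment of reads to one gene is uncertain. A total of 329 genes rose by at least 3 on the log2 scale and none fell by as much. At a threshold of 1 the numbers were 1071 higher and 77 lower.

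Falls were smaller. Optc, which encodes the matrix protein opticin, fell by 1.56 (SE 0.22, adjusted p = 1.7e-05), from 120.1 ± 10.4 to 40.2 ± 5.02 normalized reads. The growth factor gene Igf1 fell by 1.35 (SE 0.16, adjusted p = 2.2e-06; chromosome 10, 87858265 to 87937042), from 244 ± 26.8 to 95.1 ± 5.69, and Gdf5 by 1.28, from 219 ± 5.94 to 89.6 ± 5.26. Among more abundant transcripts, Pde10a fell by 1.26 (SE 0.087, adjusted p = 3.5e-09), from 3820 ± 92.9 to 1605 ± 240, Cd55 by 1.26, from 1038 ± 106 to 434 ± 57.0, and Kcnk10 by 1.28, from 713 ± 91.4 to 293 ± 26.4. Retn (-1.29), Grik2 (-1.18), Snap25 (-1.17) and Pi15 (-1.16, from 851 ± 147 to 378 ± 13.8) fell as well. Vmn1r42 (-1.40) and Vmn1r43 (-1.32) overlap each other on the genome, so it is uncertain which of these vomeronasal receptor genes the reads came from.

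In all, 6243 of 14337 tested genes passed, 2606 higher and 3637 lower (41.7% higher). The split depended on the scaling between libraries, with 53.2% higher after TMM rescaling (2979 and 2617), 60.6% with table totals (3280 and 2136), 54.1% in edgeR (3039 and 2583) and 53.6% in DESeq2 (2808 and 2430), and of the 6243 calls 1020, 1501, 1061 and 1311 were lost under these. The groups did not overlap for 61.8% of genes, where chance gives 20%.

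**Figure D2:**
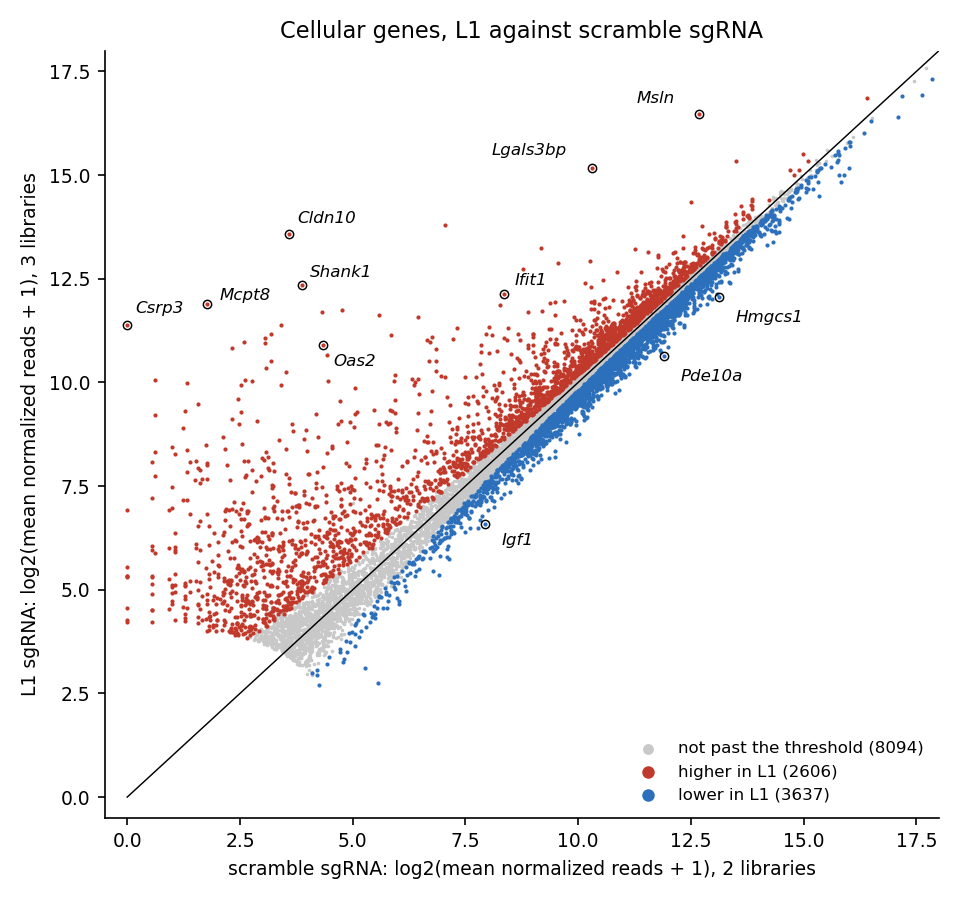
Log2 of the mean normalized read count plus 1 of each tested gene, LINE-1 sgRNA libraries (vertical axis) against scramble libraries (horizontal axis), with genes that passed in red (higher) and blue (lower) and the diagonal marking equal levels. Rises of at least 3 on the log2 scale (329 genes) start mostly from low scramble levels, and no gene fell by as much.

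Interferon-stimulated genes rose almost as a whole. Of 57 tested, 55 passed as higher and none as lower, with a median change of 1.60 (camera adjusted p = 6.0e-41; adjusted p = 0.105 with an estimated correlation). Lgals3bp rose 29.3-fold, from 1266 ± 62.1 to 37078 ± 814 normalized reads (log2 4.87, SE 0.053, adjusted p = 8.9e-20; chromosome 11, 118392751 to 118402092). Ifit1 rose 13.9-fold, from 325 ± 35.5 to 4512 ± 245 (log2 3.79, SE 0.074, adjusted p = 1.2e-16; chromosome 19, 34640871 to 34650009), Oasl2 14.5-fold, from 102 ± 11.8 to 1475 ± 81.4, and Xaf1 9.34-fold, from 248 ± 12.4 to 2313 ± 102. Oas2, singled out after its values were seen, rose from 19.2 to 1905 normalized reads (log2 6.63). Ifit2 (0.04, from 1035 ± 50.8 to 1061 ± 50.6) and Cxcl10 (0.63, adjusted p = 0.11) did not pass. Genes that sense nucleic acids rose more modestly: 17 of 24 were higher and none lower, with a median of 0.52 (camera adjusted p = 1.4e-06; adjusted p = 0.105 with an estimated correlation). Ddx58, the gene of the RNA sensor RIG-I, rose by 1.67 (from 954 ± 63.6 to 3042 ± 51.3), Dhx58 by 1.25, Eif2ak2 by 0.99 and Irf3 by 0.73, and 5 of the sensing genes are also in the interferon list.

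Cholesterol synthesis genes fell together, 23 of 25 lower and none higher, with a median of -0.78 (camera adjusted p = 6.3e-15; adjusted p = 0.105 with an estimated correlation). Hmgcs1 fell by 1.06 (SE 0.054, adjusted p = 5.1e-11; chromosome 13, 119690379 to 119708260), from 8960 ± 473 to 4288 ± 85.8 normalized reads, Fdps by 1.02, from 5219 ± 215 to 2579 ± 84.4, Cyp51 by 0.93 and Msmo1 by 0.83. Fibroblast matrix genes also fell, 32 of 44 lower and 2 higher, with a median of -0.44 (camera adjusted p = 3.3e-09; adjusted p = 0.275 with an estimated correlation). Tnc fell by 0.95 (SE 0.063, adjusted p = 2.0e-09), Dcn by 0.92 (from 3796 ± 333 to 2009 ± 140), Fbln5 by 0.80 and Thbs2 by 0.68, while in the same list Mfap2 (1.99) and Col5a3 (0.39), singled out after their values were seen, rose. Of 26 myofibroblast, SRF and YAP target genes, 16 were lower and none higher, with a median of -0.28 (camera adjusted p = 1.8e-05; adjusted p = 0.275 with an estimated correlation), led by Amotl2 (-0.67), Tpm1 (-0.63), Ankrd1 (-0.56) and Cnn2 (-0.51).

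**Figure D3:**
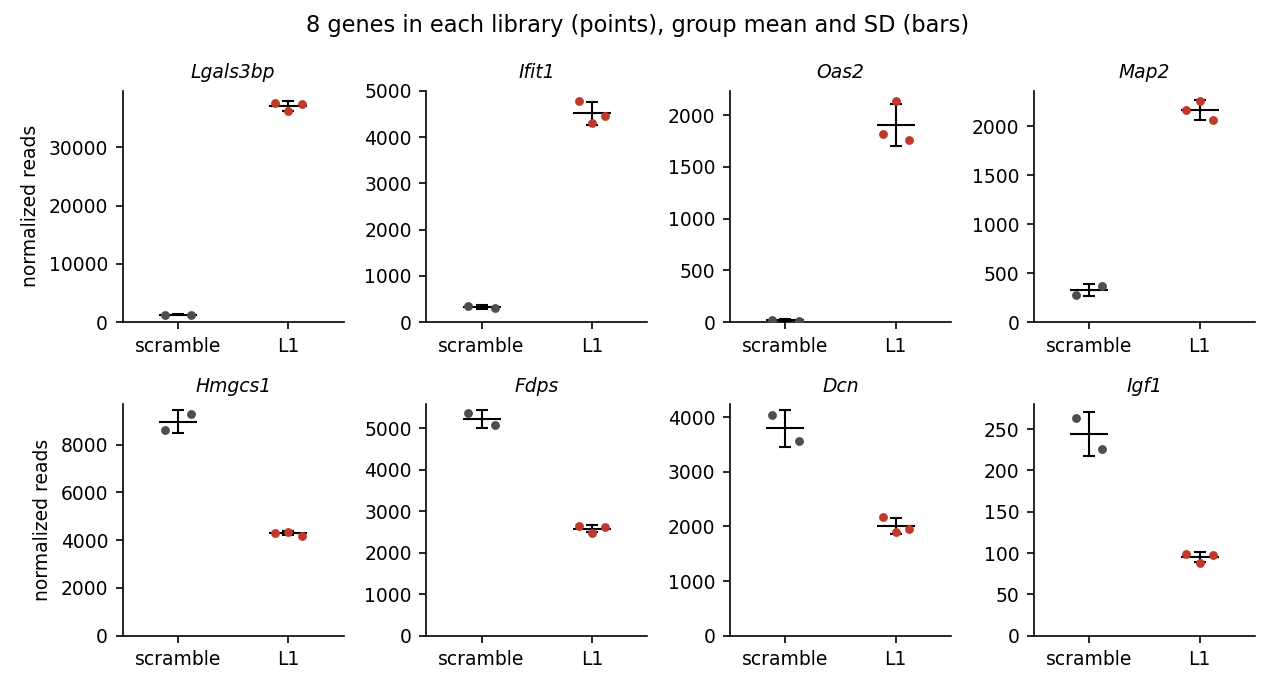
Normalized reads of Lgals3bp, Ifit1, Oas2, Map2, Hmgcs1, Fdps, Dcn and Igf1 in each library (points) with group mean and SD (bars), each axis starting at 0. In each of the 8 genes the libraries of the groups do not overlap, and Hmgcs1 went from 8960 to 4288 normalized reads.

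Ribosomal protein genes were lower by a small amount, 39 of 54 with none higher and a median of -0.24 (camera adjusted p = 6.7e-07; adjusted p = 0.532 with an estimated correlation). Rps4x (-0.37), Rps24 (-0.36), Rpl22 (-0.36) and Rpsa (-0.28) had the smallest p, and the number lower fell to 27 after TMM rescaling, 21 with table totals, 28 in edgeR and 27 in DESeq2. Glycolysis and hypoxia genes had 18 lower and 4 higher of 30, with a median of -0.22 (camera adjusted p = 0.036; adjusted p = 0.272 with an estimated correlation; 0.059 without LINE-1 sgRNA library 1, where leaving out a library gave 0.037 to 0.059). The split was 13 lower and 4 higher after TMM rescaling and in DESeq2, 13 and 6 in edgeR, and 11 and 7 with table totals. In that list Ndrg1 (-0.64), Ddit4 (-0.60) and Eno1 (-0.45) fell and Pfkfb4 (1.28) rose.

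**Figure D4:**
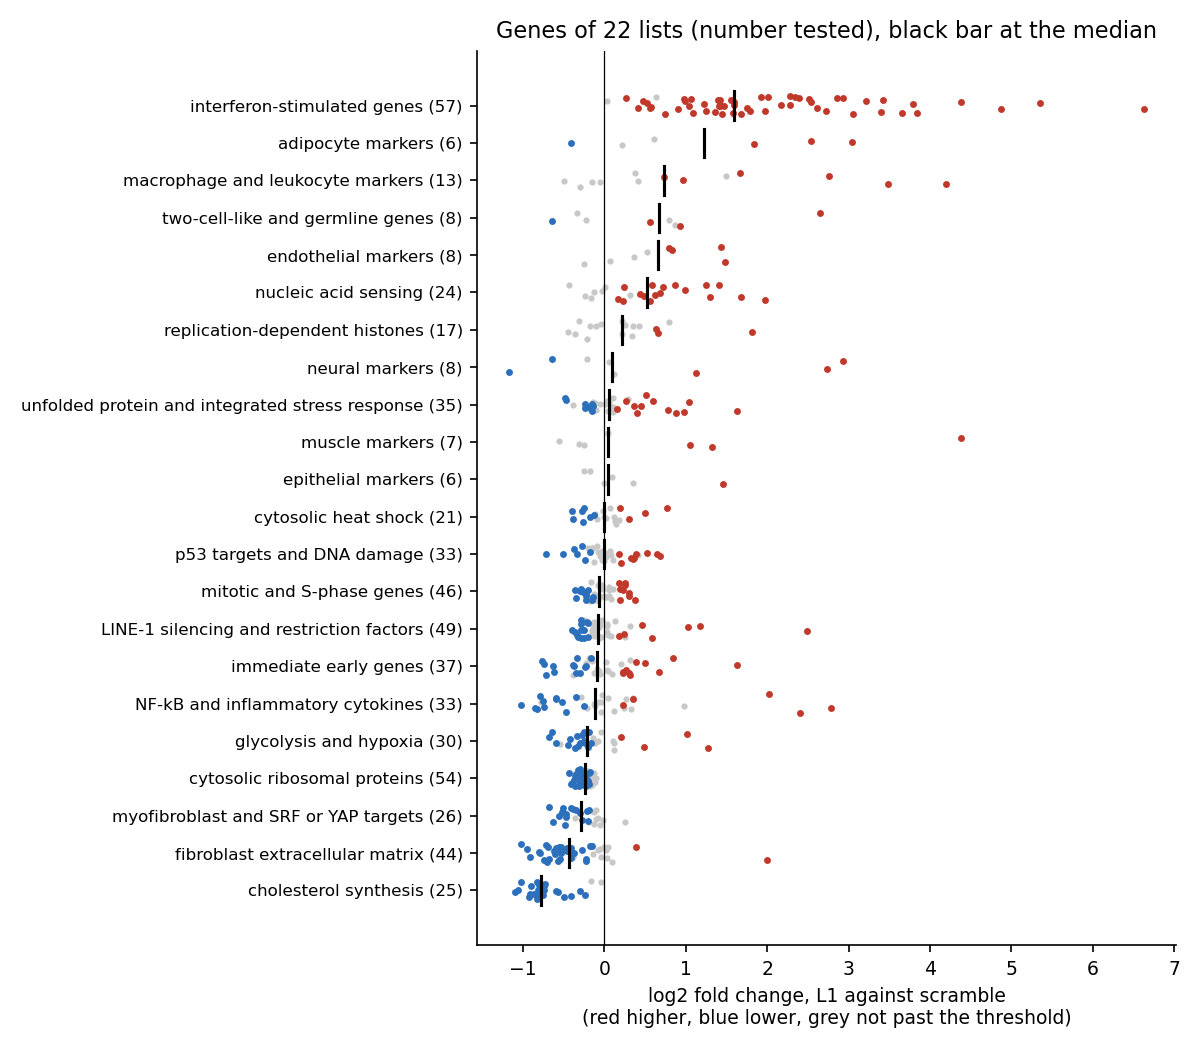
Log2 changes of the members of each gene list, with a black bar at the list median, red and blue points for genes that passed as higher and lower and grey for the rest. Interferon-stimulated genes have the highest median of the lists, 1.60, and cholesterol synthesis genes the lowest, -0.78.

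Stress and growth lists had calls in both directions and did not pass as sets, and for unfolded protein, immediate early, heat shock and mitotic genes the split of higher and lower calls depended on the scaling. Unfolded protein and integrated stress response genes had 12 higher and 9 lower of 35 (14 and 4 after TMM rescaling, 15 and 4 in edgeR, 13 and 4 in DESeq2, 17 and 4 with table totals; median 0.06, camera adjusted p = 0.089, but 0.047 without LINE-1 sgRNA library 2, where leaving out a library gave 0.047 to 0.170), with rises of Atf3 (1.63, from 188 ± 11.6 to 586 ± 35.8), Ppp1r15a (1.04), Trib3 (0.98) and Sdf2l1 (0.87). Among NF-kB and inflammatory genes, 5 were higher and 12 lower of 33 (camera adjusted p = 0.322): Mmp13 rose (2.78, from 20.2 ± 9.29 to 138 ± 4.91), and Cxcl5 (-1.03), Bcl3 (-0.82) and Vcam1 (-0.59) fell. Immediate early genes had 10 higher and 13 lower of 37, with a median of -0.09 (camera adjusted p = 0.675). The split was 10 and 10 after TMM rescaling, in edgeR and in DESeq2, and 11 and 9 with table totals. Atf3, also in this list, had its largest change (1.63), and Nr4a1 (-0.76), Nr4a2 (-0.75) and Zfp36l1 (-0.63) fell. Of 33 p53 targets, 9 were higher, among them Mdm2 (0.64) and Trp53inp1 (0.52), and 7 lower, among them Btg2 (-0.72) and Plk2 (-0.50). Cytosolic heat shock genes had 4 higher and 7 lower of 21 (7 and 5 after TMM rescaling and in edgeR, 7 and 4 in DESeq2, 8 and 4 with table totals), with Hmox1 (0.78), Dnajb1 (0.50) and Stip1 (0.30) up and Hspd1 (-0.40) down. In the mitotic and S-phase list, 9 were higher and 14 lower of 46 (median -0.07, but 13 and 6 with a median above 0 with table totals; camera adjusted p = 0.583): Mcm5 (0.37) and Mcm2 (0.30) rose, and Tk1 (-0.34) and Top2a (-0.30) fell.

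Genes of the LINE-1 silencing and restriction list went both ways, 7 higher and 13 lower of 49 (camera adjusted p = 0.583). With table totals the split was 10 and 8. The RNA editing gene Adar rose by 1.18 (from 2476 ± 70.7 to 5603 ± 122), Trex1 by 1.03 (from 311 ± 5.33 to 636 ± 14.9) and Zc3hav1 by 0.59, and the histone methyltransferase gene Setdb1 fell by 0.39. Median, mean and test differed in sign in 4 lists. Among them were NF-kB genes (-0.12, 0.02 and down) and the LINE-1 silencing and restriction list (-0.08, 0.03 and down). The others were p53 targets (-0.004, 0.03 and up, camera adjusted p = 0.675) and heat shock genes (-0.002, 0.02 and up, camera adjusted p = 0.694). The p53 and heat shock medians turned positive after TMM rescaling, with table totals, in edgeR and in DESeq2. The median of the LINE-1 silencing and restriction list did so with table totals. Replication-dependent histones had 3 higher and none lower of 17 (camera adjusted p = 0.322), Hist1h2bg (1.81), Hist1h2be (0.65) and Hist1h2bc (0.63), with Hist1h2ac (0.80, adjusted p = 0.10) not passing, except without the variance trend (0.016). Of 8 tested genes of the 2-cell-like and germline list, Tdrd9 (2.65, from 32.3 ± 5.82 to 208 ± 21.4), Tex14 (0.94) and Sp110 (0.56) rose and Sycp1 (-0.64) fell (camera adjusted p = 0.322). Without scramble library 2, Sp110 and Hist1h2bc no longer passed (adjusted p = 0.081 and 0.115). The same held for Sp110 without LINE-1 sgRNA library 3 (0.052) and for Tex14 without the variance trend (0.056). None of the 13 mitochondrially encoded transcripts is in the table.

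Markers of other cell types rose in several lists. Cd52, Plin4, Egfl7, Ovol1 and Esrp2 overlap another gene of the table, so their reads cannot be assigned to one gene with certainty. The leukocyte list had 6 higher and none lower of 13 (median 0.74, camera adjusted p = 0.021; adjusted p = 0.272 with an estimated correlation), with Cd52 going from 3.05 ± 1.74 to 70.4 ± 10.5 (log2 4.20) and Adgre1 (3.48), Laptm5 (2.76) and Cd68 (0.74) rising. Adipocyte markers had 3 higher and 1 lower of 6 (median 1.23, camera adjusted p = 0.029; adjusted p = 0.272 with an estimated correlation): Fabp4 (3.05), Pparg (2.54) and Plin4 (1.84) rose and Lpl (-0.41) fell. Endothelial markers had 4 higher and none lower of 8 (median 0.66, camera adjusted p = 0.029; adjusted p = 0.272 with an estimated correlation; 0.052 after TMM rescaling and 0.053 without scramble library 2, where leaving out a library gave 0.019 to 0.053), namely Erg (1.49), Egfl7 (1.43, from 287 ± 42.2 to 778 ± 98.5), Vwf (0.83) and Flt1 (0.80). Vwf did not pass without scramble library 2 (0.57, adjusted p = 0.175), without LINE-1 sgRNA library 2 (0.67, adjusted p = 0.113), with no filter or in DESeq2. Erg did not pass without scramble library 2 (1.04, adjusted p = 0.080) or without the variance trend. Muscle markers did not pass as a set (3 higher of 7, camera adjusted p = 0.076), but Des rose from 99.1 ± 11.5 to 2084 ± 41.3 (log2 4.38). Tnnt2 (1.33) and Tnni1 (1.05) rose too, while Tnnt3 (-0.55) did not pass. Nor did neural markers (3 higher and 2 lower of 8, camera adjusted p = 0.543), where Map2 (2.73, from 328 ± 65.7 to 2168 ± 99.2) and Rbfox3 (2.93) rose and Snap25 and Slc1a3 (-0.64) fell. Epithelial markers did not pass either (camera adjusted p = 0.583), where Ovol1 (1.46) rose and Krt8 (0.35), Esrp2 (-0.18) and Krt14 (-0.25) did not pass.

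Adjusted over the list alone, the counts of the gene lists were the same except for sensing genes (1 lower), unfolded protein and integrated stress genes (13 higher and 10 lower), heat shock genes (5 higher), mitotic and S-phase genes (15 lower), immediate early genes (15 lower), glycolysis and hypoxia genes (20 lower) and ribosomal protein genes (46 lower). Altogether 10 of 22 lists passed in camera, 5 up and 5 down.

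Single ERV loci, which ERVMap counts one by one, gave no call. In limma 0 of 16 tested loci passed, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.16. On recovered reads 0 passed in edgeR, with 3 at an unadjusted p under 0.05, and 0 in DESeq2, with 0 at that level. Those with the smallest p were Mpmv7 (-0.87, from 21.8 ± 2.52 to 11.5 ± 2.01 normalized reads) and Mpmv8 (0.87, from 10.1 ± 3.94 to 18.9 ± 5.05), which did not pass. The median over the 16 loci was -0.17, and it was -0.02 after TMM rescaling, -0.44 without scramble library 1 and -0.04 without scramble library 2. Levels this low limit the table to large changes, since only the 16 tested of the 50 loci averaged at least 10 normalized reads.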

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

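All alternatives were fixed before the data were examined, except the repeat groups formed from name starts and the placing of the L1Lx names, which were chosen after seeing the data. Of 2299 values of 155 named genes and repeats under the alternatives, 0 passed in the opposite direction, and 20 changed sign without passing in either fit. The count of 6243 cellular genes ranged from 4558 without the variance trend to 6573 with the replicate block, and leaving out a library gave 5109 (without LINE-1 sgRNA replicate 1) to 5957 (without LINE-1 sgRNA replicate 2). Of the same 6243 genes, 5182 were kept with their direction in edgeR, 4932 in DESeq2, 5223 after TMM rescaling, 4742 with table totals and 4355 without the trend. The 8 L1Md subfamilies numbered 8 or 9 in every setting, 9 with a mean of at least 50, after TMM rescaling, with table totals and without LINE-1 sgRNA replicate 2.

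The repeat calls depended more on the settings. Of 156, 77 passed without the variance trend, and leaving out a library gave 62 (without scramble replicate 2) to 180 (without LINE-1 sgRNA replicate 2), with 102 without scramble replicate 1; leaving out a scramble library leaves 1 in that group, and for the trend the cause was not tested. DESeq2 passed 104, edgeR 150. The named repeats and genes that no longer passed were most numerous without scramble replicate 2 (11), in DESeq2 (6), without scramble replicate 1 (5) and without the trend (5).

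Set tests differed between camera with a preset and camera with an estimated correlation. With an estimated correlation 0 of 22 gene lists and 0 of 13 repeat groups passed, against 10 and 4 at the preset 0.01. Lists with an estimate below the preset lost their call too, such as nucleic acid sensing (0.002), leukocyte (-0.016), endothelial (-0.121) and adipocyte markers (-0.155). In those lists a higher correlation cannot be the reason. With an estimate, camera takes its degrees of freedom from the 5 libraries rather than from the number of tested genes or repeats. That alone raises its p, so a lost call is not by itself evidence that members of a set are correlated. The share of each in the losses was not tested. In fry, which asks only whether a set moves and does not compare it with other genes, 15 lists and 3 groups passed. Leaving out a library gave 9 (without scramble replicate 2) to 11 (without LINE-1 sgRNA replicate 2) lists, and 2 (without scramble replicate 2) to 6 (without scramble replicate 1) groups. TMM rescaling gave 9 lists and 5 groups, and counting L1Lx names as rodent LINE-1 gave 4 groups.

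With the replicate block, 6573 genes, 210 repeats, 8 L1Md subfamilies, 0 ERV loci, 7 lists and 5 groups passed. Leukocyte, adipocyte and endothelial markers and glycolysis and hypoxia genes did not pass in that fit (adjusted p = 0.154, 0.155, 0.163 and 0.155) and muscle markers did (0.0015), while among groups DNA transposons did not (0.074) and simple repeats (0.0018) and tRNA (0.018) did. Whether equal numbers mark pairs stays open. Deviations from the group means of libraries with the same number correlated across genes at -0.008 and 0.066, and across repeats at 0.051 and 0.118. LINE-1 sgRNA library 3 and scramble library 1, with different numbers, gave 0.073 and 0.061. The check is weak, since the 2 scramble deviations mirror each other, and genes and repeats are not independent replicates. The block fit also passed more genes and repeats than the main fit (6243 and 156), so pairing is not excluded. ERV loci gave 0 calls in limma under each of its alternatives, with 2 at an unadjusted p under 0.05 as reported, and 0 in edgeR and DESeq2, with 3 and 0 at that level. With no filter, 122 of 4009 repeat names and 6303 genes passed.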

Other observations

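In this part, the tests on shared reads, on an equal fold of all L1Md subfamilies, on other cell types, with their abundant transcripts, on neighbouring genes and on leukocytes, and the searches for the largest rises in reads, interferon genes and gene families, were chosen only after the result was seen. By the number of reads gained, the largest rise was in Msln, the mesothelin gene, from 6578 ± 243 to 91815 ± 793 normalized reads (SD, n = 2 and n = 3; 14.0-fold; GRCm38 chromosome 17, 25748613 to 25754378). Lgals3bp, given above, gained the next most reads, followed by Actb, from 87328 ± 1107 to 118658 ± 387 (1.36-fold). Lgals3 rose from 11593 ± 1045 to 41636 ± 3100 (3.59-fold) and Slc25a24 from 5760 ± 415 to 20975 ± 130.4. Plec rose from 32299 ± 3980 to 46554 ± 480 (1.44-fold). Akr1c18, a progesterone-metabolizing enzyme gene, rose from 132 ± 16.8 to 14243 ± 516 (108-fold). The adhesion receptor gene Adgrg1, which gained fewer reads, rose from 576 ± 54.4 to 9691 ± 103. Interferon genes themselves were close to absent: 15 alpha and beta interferon genes are listed, and none exceeded 2.14 normalized reads in any library. Several of the 15 have identical values in every library, so they are not 15 separate measurements. The exception among interferon genes was Ifnz on chromosome 4 (88782131 to 88783592), which went from 2.06 ± 1.63 to 61.1 ± 7.95 (adjusted p = 9.5e-08), whereas the lambda genes Ifnl2 and Ifnl3, with identical values, went from 11.2 ± 2.18 to 9.38 ± 1.47 without passing.

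Of 185 families of genes that share a symbol stem, 7 passed in camera, and all had an adjusted p of 0.971 with an estimated correlation. Wnt ligand genes had 7 higher and none lower of 12 (adjusted p = 0.049), among them Wnt8b, from 9.36 to 393 normalized reads, and Wnt3 (log2 4.54). Synaptotagmin genes had 5 higher and none lower of 10 (adjusted p = 0.026), among them Syt14, from 3.64 to 258, and Syt1, from 6.69 to 64.6. The others were the Ifi (11 higher of 12), Parp (7 higher and 2 lower of 12), Unc (5 higher and 1 lower of 12), Rpl (31 lower of 52) and Rps (29 lower of 43) stems. Among retroviral repeats, MMVL30-int fell by 0.66 (from 10107 ± 901 to 6388 ± 382), RLTR1B-int by 0.64 and MuRRS4-int by 0.60.

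The 8 scarce L1Md subfamilies rose by 320.1 to 355 normalized reads each. Their recovered reads differed within groups far less than independent counts would, with a chi-square of 0.0395 per degree of freedom, while 1000 draws of 8 other repeat names gave no value under 0.80, so the same reads counted for several subfamilies may account for the equal rises. Scaling between the libraries is argued against, because the lowest change of the 8 was 0.71 over the deposited scaling, TMM rescaling, table totals, edgeR and DESeq2. An equal fold in all L1Md subfamilies is argued against by the highest change among the other 17, 0.26, but in 13 of those 17 a group's SD exceeds 355 normalized reads, so that an equal gain in reads would not be detectable there. Whether the rises of the 8 come from few activated copies stays open, since no positions of repeats are given.

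Of all genes, 329 rose at least 8-fold, from a median of 5.32 to a median of 139 normalized reads, and 228 of them had a scramble mean under 10. Among the 329 are markers of other cell types, 2 of leukocytes (Cd52 and Adgre1), 1 of adipocytes (Fabp4) and 1 of muscle (Des). By reads gained, 2 endothelial, 1 adipocyte, 2 muscle and 1 neural marker rose by at least the median of the 329. Of the 6 lists, 3 passed as raised, but such cells as the general source are argued against. The highest median rise of a list was 0.0555 of that of the 329 genes, though these were picked for their rises, which lowers the ratio. Some transcripts abundant in these cells stayed low, with LINE-1 sgRNA means of 14.5 for Lyz2, 8.87 for Tyrobp, 7.71 for Krt18, 16.0 for Cdh5, 1.71 for Adipoq, 10.3 for Ckm and 17.7 for Gfap. Other markers of the lists were high, such as Map2 (2168), Des (2084) and Egfl7 (778). Cell types outside the 6 lists, such as mast cells and basophils, were not examined. Reads of an overlapping gene are argued against as the general source, since 14.0% of the genes with 1 position overlap another gene, and stay open for those. A change spreading along the chromosome remains open: 38 had an unrelated raised gene within 100 kb, against a median of 20 and a highest of 44 in 1000 draws from all genes at the same scramble level, but a median of 33 and a highest of 57 in draws from tested genes only. Activation by guides bound at or near these genes, LINE-1 insertions in or near them and a response to LINE-1 RNA could each give such rises and were not analysed here, because guide sequences and repeat positions are not given and each group has 1 guide set.

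Interferon-stimulated genes rose with a median of 1.60. A general rise of genes expressed at this level is argued against, since the highest median of 10000 lists matched on mean level was 0.13. RNA from leukocytes as a whole is argued against too. The median rise of 15 leukocyte markers was 0.0130 of that of the interferon list (7.22 against 555 normalized reads). Of these markers, 13 were above the filter in these cells and 0 are in the interferon list. The leukocyte list itself passed as raised, with 6 higher and none lower of 13. It mixes markers of several leukocyte types, so its median cannot exclude RNA from a single type. A response of the cells to LINE-1 RNA or its products is a hypothesis that these values do not test. Several LINE-1 names rose. The 8 raised L1Md names, which may share reads, together went from 2990 ± 63.7 to 5726 ± 346 normalized reads. The summed reads of all LINE-1 names changed by -6.52%, with overlapping libraries (two-sided exact permutation p = 0.5, where no p below 0.1 is possible). LINE-1 sgRNA library 2 was the lowest at 404825, against 454526 and 463472 in LINE-1 sgRNA libraries 1 and 3. With SDs of 16797 in scramble and 31595 in LINE-1 sgRNA libraries, that sum cannot show a rise of scarce names. A response to the LINE-1 sgRNA plasmids themselves, or to a raised gene such as Ifnz, could give the same rise of interferon-stimulated genes. This design does not separate these explanations. Degrading LINE-1 RNA under the same guides would test the LINE-1 RNA hypothesis. The interferon-stimulated genes should then fall back if they respond to that RNA or its products. A fall could also come through a raised gene whose transcript carries LINE-1 sequence, which that experiment would not separate.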
